A study of Arabidopsis thaliana with 24 samples.

How the data were processed

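Poly(A) RNA of whole Arabidopsis roots was sequenced in 24 libraries, 3 from each of 8 groups. The groups were flight and ground samples of Col-0 and WS for the Virgin Galactic flight (VG) and of WS and sku5 for the Blue Origin flight (BO). Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, checked with FastQC 0.11.4 and MultiQC 1.1, aligned with STAR 2.7.3a, quantified with RSEM 1.2.31 and compared with DESeq2. The version of DESeq2 used by the authors is not given in the notes. The genome build and annotation are not given in the sources used here. Per the labels, flight libraries held ERCC spike-in mix 1 and ground libraries mix 2; spike-ins were not analysed here.

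The authors deposited 1 table of FPKM values for Col-0 (33469 genes in 6 libraries) and 1 for WS and sku5 (32844 genes in 18 libraries). That these deposited values are FPKM was read from the values themselves. They were not whole numbers, column sums ran from 1021562 to 1290752, and sums weighted by transcript length varied between libraries by a CV of 1.05% and 1.12%. The Col-0 table holds 625 genes that the other lacks, and 11372 and 8764 genes were listed at 0 in every library of the Col-0 and the WS and sku5 table. Read totals were not given, so depth per library is unknown and no interval based on counts was computed. As a rough scale, the deposited mean normalized count of 1550 genes gave a median of 33.2 per FPKM and kilobase (quartiles 29.5 and 36.2).

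The authors also deposited 4 lists of changed genes. These give, per the file headers, a log2 fold change (flight over ground), its standard error on the log2 scale, a p-value and a mean count per gene. By their size, the deposited p-value entries are adjusted values, although the header does not say so. These lists were described, and their mean counts gave the rough scale above, but no comparison here was fitted to them.

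The design written before the data were examined gave a test for counts and a test for normalized values. Since the tables hold FPKM, the second was used: limma 3.58.1 with a mean-variance trend on log2(FPKM + 1), in R 4.3.3, for genes at 1 FPKM or more in at least 3 libraries of the fit. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of 1 comparison. The 6 Col-0 libraries were fitted alone (4 residual degrees of freedom), and the 18 WS and sku5 libraries together (12 residual degrees of freedom). There were 7 comparisons: flight against ground in each of the 4 pairs of groups, sku5 against WS on the ground at BO, the difference of the BO flight effects between sku5 and WS, and the difference of the WS flight effects between BO and VG. The last 2 were interaction contrasts. Replicate numbers are not said to pair libraries, so no block was used. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The fits were tested on simulated data, with the shares of recovered changes given beside each comparison. Simulated changes were put only in genes with a mean log2(FPKM + 1) above 2, with normal noise independent between genes. Recovery in the real libraries may therefore be lower. Each simulation changed 50 genes at each of the log2 sizes 0.5, 1, 2 and 3. The adjustment of p is stricter where fewer genes change and looser where more do. The shares therefore hold only for that number of changed genes, and overstate recovery where fewer genes change.

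The lists held 406 genes in 27 lists, all written into the same design. They cover heat shock, endoplasmic reticulum folding, reactive oxygen, peroxidases, touch and calcium, early stress transcription factors, jasmonate, hypoxia, dark and sugar starvation, light, the circadian clock, cell wall enzymes, the SKU5 family, gravitropism and auxin transport, auxin response, cold with drought and abscisic acid, defence, iron, nitrate and phosphate, and reference genes. A further 7 lists mark tissues or cells: photosynthesis, root hair, root cap, endodermis, xylem, phloem and dividing cells. The member UBC9 was dropped because the reference gives its identifier another name. Lists were tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the lists of 1 comparison. Members were also counted after adjustment over the list alone.

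Genes were named by a rule set in advance. Eligible genes were called, had the 3 libraries of 1 group all above the 3 of the other, had a higher group mean at or above the median over tested genes, and had a symbol in the reference. Of these, the 10 with the largest positive and the 10 with the largest negative log2 change were named (5 and 5 for interactions, where separation was not asked). Up to 4 called members of each list by smallest p were eligible too, and SKU5, SKS1 and SKS2 always. With under 5 called genes, all were named. Symbols, transcript lengths and shared 50-base words came from the TAIR10.1 reference, in which 32835 and 32375 of the identifiers of the Col-0 and the WS and sku5 table were found. Its exon coordinates were used for the lengths and words only. Neighbouring genes in the test of a chromosome segment were taken by the order of their identifiers.

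The alternatives set in advance were a TMM factor per library, quantile normalization, no filter, a filter at 5 FPKM, pseudocounts of 0.1 and 5, limma without trend, a replicate block, a minimum log2 change of 1, a fit of only the libraries compared, and leaving out each library in turn. For shared calls an adjusted p under 0.01 was also tried. Alternatives chosen after seeing the data were genes above 0 in every library, leaving out 3 libraries that stood apart on the principal components, an adjusted p under 0.01 with a log2 change of at least 1, and photosynthesis genes as a covariate. Alternatives written for counts were not run, because no table of counts per library was used here. Raw reads were not analysed here.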

Results

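Roots of Arabidopsis thaliana seedlings were profiled by poly(A) RNA sequencing after 2 suborbital flights and in matching ground controls. The Virgin Galactic flight (VG) carried the wild types Col-0 and Wassilewskija (WS) at 10 days of age. The Blue Origin flight (BO) carried WS and sku5, a mutant in the WS background whose roots skew along the agar surface, at 11 days. Each vehicle gave about 3 minutes of microgravity between phases of raised gravity, which peaked near 4.5 g on ascent and 3.5 g on descent for VG, and near 3 g and 5.7 g for BO. The 24 libraries fall into 8 groups of 3, a flight and a ground group for each line on each vehicle. Values were deposited as FPKM (fragments per kilobase of transcript, scaled to the library total), so the read total of each library is not given in the tables used here. The authors' lists of WS and sku5 genes give a median of 33.2 normalized counts per FPKM and per kilobase of transcript over 1550 genes. Between 18176 and 18877 genes per library lay at 1 FPKM or more. Replicates of 1 group came from roots fixed in a single fixation tube, so every p-value measures only the spread between these samples.

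Among the 18 WS and sku5 libraries, the first principal component held 42.1% of the variance and separated the VG from the BO libraries. The second component held 15.2% and separated BO flight from BO ground libraries in both lines. Vehicle, year, site, age and growth conditions change together between VG and BO, so a difference between the vehicles cannot be assigned to any of them. BO flight roots were fixed 33 minutes after landing. No such time was recorded here for VG, so the time to fixation could not be compared between the vehicles. Pearson's r between replicates of 1 group, across genes, ran from 0.946 to 0.976 in these libraries and from 0.931 to 0.955 in Col-0.

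**Figure D1:**
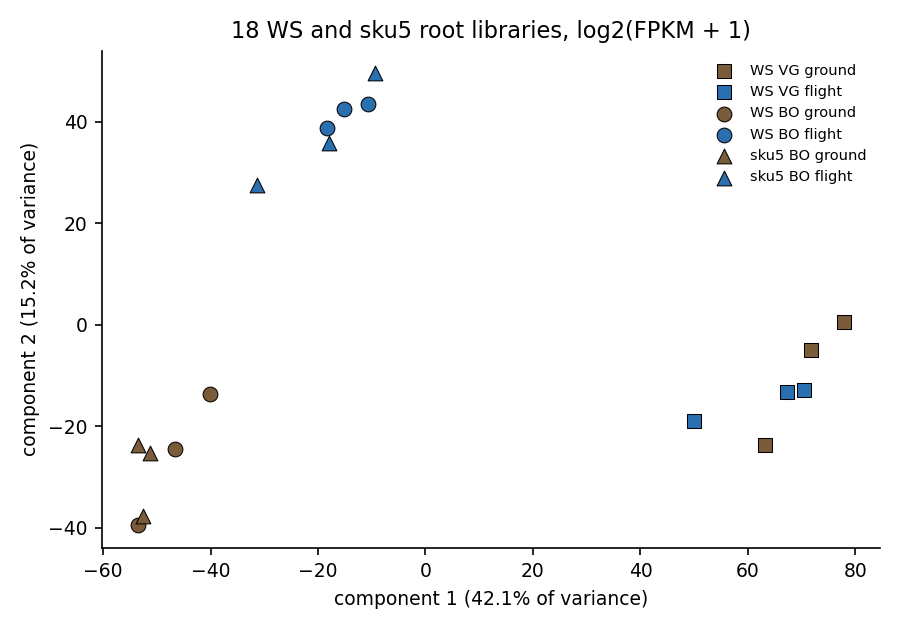
Principal components 1 and 2 of the 18 WS and sku5 libraries on the log2(FPKM + 1) scale, 1 point per library. Component 1 (42.1% of the variance) separates VG from BO, and component 2 (15.2%) separates BO flight from BO ground.

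The comparison of sku5 with WS on the ground asks what the mutation changes without flight. SKU5 is a membrane-anchored glycoprotein of the root cell wall that resembles multicopper oxidases. It is the mutated gene, so its transcript also checks the labels. The transcript was strongly reduced in the mutant, and few other genes were called. The 2 other called genes, which lie on the same arm of chromosome 5, encode a chaperone cofactor and a signalling kinase.

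SKU5 (AT4G12420) lay at 8.55 ± 1.42 FPKM (SD, n = 3) in sku5 and 84.2 ± 8.67 in WS, a log2 change of -3.16 (SE 0.24, limma adjusted p = 6.78e-06). Across all 6 sku5 libraries it ranged from 3.17 to 9.85 FPKM, below each of the 12 WS libraries, the lowest of which had 27.60. Of 20127 genes tested with limma, 3 were lower in sku5 and 0 were higher at an adjusted p under 0.05, and 435 had an unadjusted p under 0.05. With only the libraries compared, 1 gene was called. Fes1C (AT5G02150), related to nucleotide exchange factors of HSP70 chaperones, fell by 1.80 (SE 0.22, limma adjusted p = 0.0024) from 28.7 ± 5.74 to 7.56 ± 2.03 FPKM. BSK10 (AT5G01060), of the brassinosteroid-signalling kinase family, fell by 1.69 (SE 0.24, limma adjusted p = 0.0169) from 24.1 ± 2.42 to 6.97 ± 2.14 FPKM. The BSK10 call was lost without WS BO ground replicate 1 (-1.77), 2 (-1.64) or 3 (-1.65) and without sku5 BO ground replicate 1 (-1.71) or 3 (-1.48). SKS1 (AT4G25240), a close relative of SKU5, was not called (log2 change 0.13, SE 0.19). SKS2 (AT5G51480) was not tested, since it lay between 0 and 0.96 FPKM in the 24 libraries. In simulated data for this comparison, 29 of 50 genes changed by 1 on the log2 scale were recovered, and 47 of 50 changed by 2.

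Of the 27 fixed gene lists, 4 passed limma's camera test for sku5 against WS on the ground with a preset correlation between genes of 0.01. Endoplasmic reticulum folding genes lay higher in sku5 (median log2 change 0.20, adjusted p = 0.000165, and 0.541 with an estimated correlation). Hypoxia genes lay lower (median -0.24, adjusted p = 0.000173, and 0.191 with an estimated correlation), as did sugar starvation genes (median -0.21, adjusted p = 0.0132, and 0.69 with an estimated correlation). Nitrate and phosphate genes also lay lower (median -0.39, adjusted p = 0.00232, and 0.353 with an estimated correlation). Of the members of these 4 lists, 0 were called by limma, over all genes or adjusted over the list alone. The sugar starvation call was lost without WS BO ground replicate 3 (0.0647) and sku5 BO ground replicate 1 (0.597), and without WS BO ground replicate 2 its direction reversed (0.899). The nitrate and phosphate call was lost without sku5 BO ground replicate 3 (0.553) and without the 3 libraries that stood apart (0.768). The SKU5 family list had 1 member lower, SKU5 itself, and 4 not called, with 1 lower adjusted over the list alone (camera adjusted p = 0.0762). Its median was 0.06 and its mean -0.58. The other 22 lists had 0 members called by limma, over all genes or adjusted over the list alone, and camera adjusted p between 0.0523 and 0.885. Under the alternatives, 31 results of lists that had not passed did pass. Among them, defence genes passed with no filter (0.00328), a pseudocount of 0.1 (0.00667), only the libraries compared (0.0189) and genes above 0 in every library (0.0183). The root cap list had a median of -0.16 and a mean of 0.04. The number of passing lists depended on single libraries. It was 9 without WS BO ground replicate 1, 7 without WS BO ground replicate 3, 7 without sku5 BO ground replicate 1, 8 without sku5 BO ground replicate 2 and 7 without sku5 BO ground replicate 3.

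The BO flight of WS compares wild-type roots after a suborbital flight, with a rocket launch and a capsule landing, with ground controls. Flight plates were wrapped in black-out cloth, and ground plates stayed in a growth cabinet and were harvested 1 h after the flight plates, so a difference between BO flight and ground cannot be assigned to the flight alone. Roots that had flown differed widely from the ground controls. Of 17 genes that plants switch on when sugar runs short or light is absent, 15 rose, and of 12 light response genes, 7 fell and 2 rose (adjusted p = 0.187 and 0.599 with an estimated correlation). The flavonoid pathway genes TT4, FLS1, TT5 and TT7 fell.

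**Figure D2:**
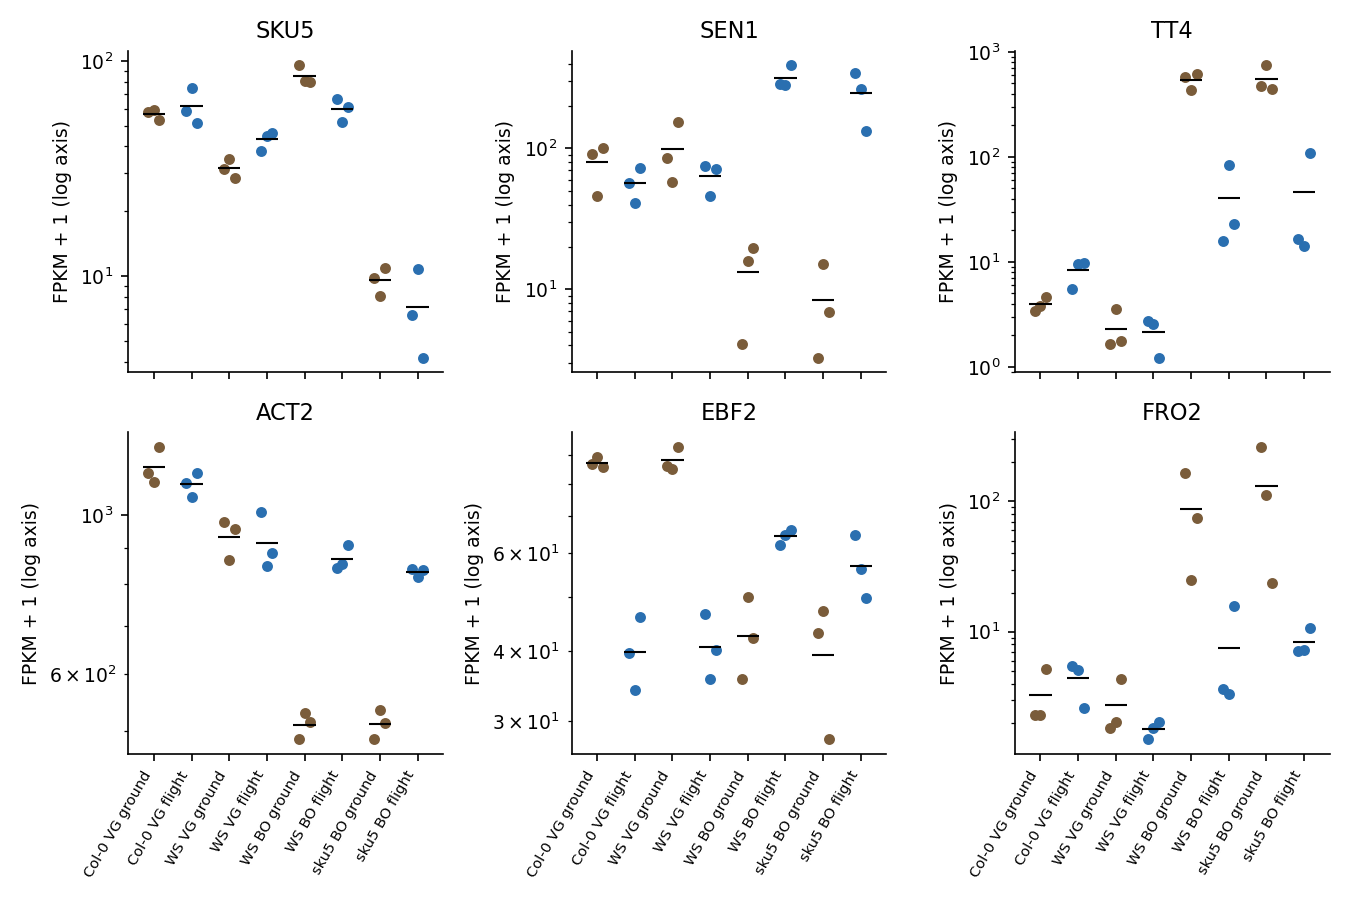
FPKM + 1 on a log axis in each of the 24 libraries for 6 genes, with ground libraries in brown, flight libraries in blue and a bar at the mean of the 3 libraries. SKU5 is low in all 6 sku5 libraries, SEN1 and ACT2 are lowest and TT4 and FRO2 highest in BO ground libraries, and EBF2 is highest in VG ground libraries.

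In WS, limma called 2345 of 20127 genes between BO flight and ground, 1108 higher and 1237 lower in flight. Of these, 471 were higher and 501 lower by at least 1 on the log2 scale. With a TMM factor per library, the split was 1374 higher and 1007 lower, or 57.7% higher against 47.2% without the factor. The count rested in part on single libraries: it was 879 without ground replicate 1, 1295 without flight replicate 3, 1351 without ground replicate 3 and 1421 without flight replicate 1. Higher counts came with only the libraries compared (3257) and without the 3 libraries that stood apart (3389). The fit recovered 28 of 50 simulated changes of 1 on the log2 scale and 48 of 50 of 2. Among the named genes, SEN1 (AT4G35770, also DIN1), a marker of senescence and darkness, rose most. It went from 12.3 ± 8.15 to 317 ± 61.2 FPKM (SD, n = 3), a log2 change of 4.85 (SE 0.57, limma adjusted p = 0.000118). BCAT-2 (AT1G10070), which starts the breakdown of branched-chain amino acids, rose by 3.70 (SE 0.62). The sugar exporter SWEET12 (AT5G23660) rose by 3.62 (SE 0.60) and the amino acid transporter UMAMIT20 (AT4G08290) by 3.26 (SE 0.53). The asparaginase ASPGB1 (AT3G16150) rose by 3.43 (SE 0.37) and MGL (AT1G64660), which degrades methionine, by 3.19 (SE 0.43). The other large rises were the ubiquitin ligase ATL8, the zinc finger gene ATCTH, the stress gene OXS3 and the salt stress gene SIS, with log2 changes from 2.81 to 3.12. Limma's adjusted p for these 10 genes lay between 6.38e-05 and 0.002.

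Among the named genes, the largest fall in WS at BO was in ELIP1 (AT3G22840), an early light-induced protein of the chloroplast. It went from 27.4 ± 7.16 to 0.0567 ± 0.0982 FPKM (SD, n = 3), a log2 change of -4.72 (SE 0.51, limma adjusted p = 0.000101). TT4 (AT5G13930), the chalcone synthase that opens the flavonoid pathway, went from 542 ± 94.4 to 39.4 ± 36.8 FPKM (log2 change -4.12, SE 0.65, limma adjusted p = 0.00104). The later pathway genes FLS1, TT5 and TT7 fell by 4.05, 3.84 and 3.24, and KAT5, a peroxisomal thiolase, fell by 3.19. FRO2 (AT1G01580), the reductase that iron uptake needs, fell by 3.56 (SE 0.77, limma adjusted p = 0.00684) from 87.1 ± 71.1 FPKM. The iron genes CYP82C4, bHLH38 and NAS1 fell by 3.75, 3.1 and 3.1. Ground values of these iron genes varied widely: FRO2 lay at 164.16, 24.03 and 73.23 FPKM in the 3 ground libraries and between 2.33 and 14.72 in flight. FRO2 was not called without ground replicate 1 (-2.91), nor bHLH38 without flight replicate 1 (-2.70), ground replicate 1 (-2.52) or ground replicate 3 (-2.88). CYP82C4 was not called without flight replicate 1 (-3.51) or 2 (-3.69) or without ground replicate 1 (-2.90) or 3 (-3.81).

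In WS at BO, 5 of the 27 lists passed camera with the preset correlation and 0 with an estimated correlation. Of 17 dark and sugar starvation genes, 15 rose, 0 fell and 2 were not called, with 16 higher adjusted over the list alone (median log2 change 1.82, camera adjusted p = 7.47e-21, and 0.187 with an estimated correlation). The trehalose phosphate synthase gene TPS9 rose by 1.68 (SE 0.20), the sugar transporter STP1 by 1.65 (SE 0.22) and AKINBETA1, a subunit of an energy-sensing kinase, by 1.71 (SE 0.24). Of 12 light response genes, 2 rose, 7 fell and 3 were not called, with 3 higher and 8 lower adjusted over the list alone (median -1.73, camera adjusted p = 0.00337, and 0.599 with an estimated correlation). BBX21, a light signalling factor, was 1 of the 2 that rose (log2 change 1.01, SE 0.14). Of 9 nitrate and phosphate genes, 0 rose, 5 fell and 4 were not called, and 5 fell adjusted over the list alone (median -1.16, camera adjusted p = 0.000448, and 0.187 with an estimated correlation). The nitrate reductase gene NIA1 fell by 2.22 (SE 0.37) and the nitrite reductase gene NIR1 by 1.27 (SE 0.26). Of 22 endoplasmic reticulum folding genes, 0 rose, 6 fell and 16 were not called, with 11 lower adjusted over the list alone (median -0.49, camera adjusted p = 0.000454, and 0.599 with an estimated correlation). The chaperone BIP1 fell by 0.93 (SE 0.24) and was not called without flight replicate 3 (-0.88) or ground replicate 1 (-0.76). Of 19 iron genes, 0 rose, 5 fell and 14 were not called, with 1 higher and 6 lower adjusted over the list alone (median -1.09, camera adjusted p = 0.0223, and 0.599 with an estimated correlation). This last call was lost without ground replicate 1 (camera adjusted p = 0.0853) and without ground replicate 3 (0.0749), with the filter at 5 FPKM (0.0702), with only the libraries compared (0.222) and with genes above 0 in every library (0.0863), where the light call was lost too (0.0702).

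The remaining 22 lists did not pass camera in WS at BO (adjusted p between 0.14 and 0.855), though single members were called. Heat shock genes had 2 higher, 5 lower and 11 not called (median -0.56, camera adjusted p = 0.14, and 0.0146 without flight replicate 2). Without 1 library, endodermis genes (0.0154 without flight replicate 2) and phloem genes (0.0378 without ground replicate 2) passed as well. HSP90.1 fell by 1.97 (SE 0.32) and the heat shock factor HSFA7A rose by 1.45 (SE 0.23). Adjusted over the list alone, 2 heat shock genes were higher and 7 lower. Hypoxia genes had 4 higher, 7 lower and 13 not called (5 higher and 10 lower adjusted over the list alone), with sucrose synthase SUS1 up by 1.12 (SE 0.20) and the haemoglobin HB1 down, a log2 change of -1.46 (SE 0.26). Clock genes had 5 higher, 3 lower and 19 not called (8 and 3 adjusted over the list alone). The evening gene ELF4 fell by 2.42 (SE 0.41), and the morning gene LCL1 (AT5G02840) rose by 1.38 (SE 0.24). Cell wall genes had 1 higher, 4 lower and 20 not called (1 and 5 adjusted over the list alone). The expansin EXPA1 fell by 1.36 (SE 0.22) and the xyloglucan enzyme gene XTH31 by 2.05 (SE 0.33). Jasmonate genes had 0 higher, 4 lower and 16 not called (2 and 6 adjusted over the list alone). Touch and calcium genes had 2 higher, 2 lower and 6 not called, the same 2 and 2 counts adjusted over the list alone. The calmodulin-like gene TCH2 (AT5G37770, also CML24) fell by 1.74 (SE 0.27).

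In the same WS comparison, reactive oxygen genes had 2 higher, 3 lower and 18 not called (2 and 3 adjusted over the list alone), and early stress transcription factors 2 higher, 0 lower and 14 not called (2 and 1 adjusted over the list alone). RBOHD, an oxidase that makes superoxide, fell by 1.14 (SE 0.21), and the transcription factor gene WRKY40 rose by 1.41 (SE 0.25). Gravitropism and auxin transport genes had 0 higher, 2 lower and 12 not called (0 and 2 adjusted over the list alone). Auxin response genes had 1 higher, 1 lower and 16 not called (1 and 1 adjusted over the list alone). The peroxidase list had 0 higher, 1 lower and 14 not called (0 and 0 adjusted over the list alone), and the defence list 0 higher, 1 lower and 5 not called (0 and 1 adjusted over the list alone). SKS1 was the 1 member of the SKU5 family list that fell, by 0.63 (SE 0.19, limma adjusted p = 0.0407), with 4 not called and 1 lower adjusted over the list alone. SKS1 was not called without flight replicate 1 (-0.55) or 3 (-0.59) or without ground replicate 1 (-0.56), 2 (-0.69) or 3 (-0.66). SKU5 was not called (log2 change -0.51, SE 0.24, limma adjusted p = 0.194), except where only the 6 libraries compared were fitted. Of 16 cold, drought and abscisic acid genes, 0 were called by limma, over all genes or adjusted over the list alone. Among the tissue markers, photosynthesis genes had 1 higher of 21, endodermis genes 1 higher of 9 and phloem genes 1 higher of 4, while root hair (9), root cap (3), xylem (6) and dividing-cell (8) genes had 0 called by limma. Adjusted over the list alone, these 7 marker lists gave the same counts. For auxin response, photosynthesis, root hair and xylem genes, the median, the mean and the camera direction did not share a sign. Among 7 reference genes, ACT2 (AT3G18780) rose by 0.77 (SE 0.11) from 510 ± 21.8 to 867 ± 33.6 FPKM, GAPC2 fell by 0.49 (SE 0.15) and 5 were not called, with 2 higher and 1 lower adjusted over the list alone. GAPC2 was not called without flight replicate 1 (-0.50), 2 (-0.46) or 3 (-0.51), without ground replicate 1 (-0.41) or 3 (-0.44), with a TMM factor (-0.43) or with quantile normalization (-0.41). ACT2 also rose with a TMM factor (0.83) and with quantile normalization (0.85).

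The BO flight of sku5 asks the same of roots that lack normal SKU5 function. Of 17 sugar starvation genes, 15 rose, and of 12 light response genes, 7 fell and 2 rose (adjusted p = 0.256 and 0.701 with an estimated correlation). The flavonoid pathway genes TT4, FLS1, TT5 and TT7 fell. SKU5 itself was low in both sku5 groups.

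In sku5, limma called 2072 of 20127 genes between BO flight and ground, 1016 higher and 1056 lower in flight, and 480 and 449 of these by at least 1 on the log2 scale. With a TMM factor per library, the split was 1338 higher and 795 lower, or 62.7% higher against 49.0% without the factor. The count was 1082 without flight replicate 1, 1095 without ground replicate 1, 1366 without flight replicate 2, 1369 without ground replicate 2 and 942 with only the libraries compared. Of 50 simulated changes of 1 on the log2 scale 31 were recovered, and of 50 changes of 2, 49. SEN1 rose from 7.43 ± 6.06 to 245 ± 105 FPKM (SD, n = 3; log2 change 5.04, SE 0.57, limma adjusted p = 9.31e-05). Of the other 9 largest rises among the named genes, 7 were also among the 10 largest named in WS, with log2 changes from 3.01 to 3.52 in sku5. The cation exchanger CHX17 (AT4G23700) rose by 3.15 (SE 0.33) and CCL (AT3G26740), a transcript under clock control, by 2.92 (SE 0.61). FLS1 fell by 4.30 (SE 0.50) and TT4 fell by 4.2 (SE 0.65). TT5 fell by 3.59 (SE 0.50), ELIP1 fell by 3.51 (SE 0.51) and ELIP2 fell by 3.29 (SE 0.52). TT7 and KAT5 fell by 3.43 and 3.04, FRO2 fell by 3.44 and CYP82C4 fell by 3.88. FRO2 was not called without ground replicate 1 (-2.66), and CYP82C4 was not called without flight replicate 1 (-3.88) or 2 (-3.76) or ground replicate 1 (-2.57) or 2 (-3.57). SKU5 was not called (log2 change -0.51, SE 0.24, limma adjusted p = 0.204), but was called without flight replicate 2 (-0.85).

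MT1A (AT1G07600), a metallothionein, was called lower in sku5 flight because it was listed at 0 in all 3 flight libraries. It was listed at 27513, 20952 and 9906.2 FPKM in the 3 sku5 ground libraries and at 0 in WS BO flight replicate 2, beside 13065 and 18812 in the other 2 libraries of that group. All 50-base words of its annotated exons occur in another annotated gene, so its value is uncertain, and no fold is given. The neighbouring metallothionein MT1C (AT1G07610) lay between 1444.5 and 2197.4 FPKM in the sku5 flight libraries.

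In sku5 at BO, 7 lists passed camera with the preset correlation and 0 with an estimated correlation. Dark and sugar starvation genes again had 15 higher and 2 not called, with 16 higher adjusted over the list alone (median 1.81, camera adjusted p = 2.78e-21, and 0.256 with an estimated correlation). Light response genes had 2 higher, 7 lower and 3 not called, with 3 and 7 adjusted over the list alone (median -2.13, camera adjusted p = 0.0111, and 0.701 with an estimated correlation). Endoplasmic reticulum folding genes had 3 lower and 19 not called, with 8 lower adjusted over the list alone (median -0.45, camera adjusted p = 0.00613, and 0.701 with an estimated correlation), and this call was lost without flight replicate 1 (0.114). Nitrate and phosphate genes had 2 lower and 7 not called, with 4 lower adjusted over the list alone (median -1.08, camera adjusted p = 0.0111, and 0.445 with an estimated correlation). Heat shock genes had 2 higher, 4 lower and 12 not called, with 2 and 8 adjusted over the list alone (median -0.67, camera adjusted p = 0.043, and 0.701 with an estimated correlation). Iron genes had 3 lower and 16 not called, with 7 lower adjusted over the list alone (median -0.75, camera adjusted p = 0.043, and 0.701 with an estimated correlation). Phloem markers had 1 higher and 3 not called, the sucrose loader SUC2, which rose by 1.48 (SE 0.26), also 1 adjusted over the list alone (median 0.75, camera adjusted p = 0.043, and 0.445 with an estimated correlation). Only 3 lists passed without flight replicate 1 and 4 without ground replicate 2. The nitrate and phosphate call was lost without ground replicate 2 (0.0902). The heat shock call was lost without flight replicate 1 (0.0524) or 2 (0.205) or ground replicate 1 (0.142) or 2 (0.181). The iron call was lost without the same 4 libraries (0.0524, 0.205, 0.229 and 0.162). The phloem call was lost without flight replicate 1 (0.0727) or ground replicate 2 (0.0902) or 3 (0.0693). Heat shock, iron and phloem genes also lost their calls with the filter at 5 FPKM (0.253, 0.153 and 0.166), with the replicate block (0.0811, 0.0678 and 0.0678) and with genes above 0 in every library (0.162, 0.201 and 0.162), where light genes did so too (0.0549). With only the libraries compared, iron (0.118) and phloem genes (0.0647) lost theirs, as did heat shock genes with a pseudocount of 0.1 (0.181), iron genes with 5 (0.0671) and phloem genes without the 3 libraries that stood apart (0.104).

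The other 20 lists did not pass camera in sku5 at BO (adjusted p between 0.152 and 0.852). Limma called 1 higher and 6 lower of 25 cell wall genes (2 and 6 adjusted over the list alone). It called 4 and 4 of 27 clock genes (7 and 4 adjusted over the list alone), 4 and 4 of 24 hypoxia genes (4 and 8), 1 and 4 of 20 jasmonate genes (1 and 6) and 3 and 2 of 23 reactive oxygen genes (3 and 3). XTH31 fell by 2.26 (SE 0.33), ELF4 by 2.64 (SE 0.41) and RBOHD by 1.52 (SE 0.21), and SUS1 rose by 1.24 (SE 0.20). Of 16 early stress transcription factors, 2 were higher and 1 lower (2 and 2 adjusted over the list alone). Auxin response genes had 2 higher and 1 lower of 18 (2 and 1), and touch genes 1 higher and 2 lower of 10 (2 and 2). Photosynthesis genes had 2 higher of 21 (2 adjusted over the list alone), and passed camera without flight replicate 2 (0.0471) or ground replicate 2 (0.0169). Among peroxidase, gravitropism and dividing-cell genes, 1 of each list was lower, against 1 higher and 2 lower, 3 lower, and 1 lower adjusted over the list alone. In the SKU5 family list SKS1 fell by 0.71 (SE 0.19, limma adjusted p = 0.0251), with 2 lower adjusted over the list alone. Its call was lost without flight replicate 1 (-0.55) or 2 (-0.72) or ground replicate 1 (-0.72), 2 (-0.71) or 3 (-0.71). ACT2 was the 1 reference gene called (log2 change 0.70, SE 0.11, with 0.78 under a TMM factor and 0.63 under quantile normalization), with 2 higher adjusted over the list alone. Cold, defence, root hair, root cap, endodermis and xylem genes had 0 called by limma, over all genes or adjusted over the list alone. The median, the mean and the camera direction did not share a sign for reactive oxygen, early stress, defence, endodermis, cold and reference genes.

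The same flight carried both lines, so their responses can be set side by side. Flight and ground libraries differed in many shared genes, in the same direction in WS and sku5, with the same wrapping and harvest times in both lines. No single gene passed the test for a different response in the mutant.

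Of the genes called in WS at BO, 787 were higher and 671 lower in sku5 as well, where independent lists of those sizes would share 55.9 and 64.9. The number called in opposite directions was 0. Of the 2345 genes called in WS, 99.2% changed in the same direction in sku5, and Pearson's r of the log2 changes was 0.777 across 20127 genes, which are not independent replicates. The shared higher genes numbered 430 without WS BO ground replicate 1, 466 without sku5 BO flight replicate 1 and 495 without sku5 BO ground replicate 1. The shared lower genes numbered 316, 377 and 394 without the same 3 libraries, 415 without sku5 BO ground replicate 2, 422 without WS BO flight replicate 3, 433 without WS BO ground replicate 3 and 437 without WS BO flight replicate 1. With only the libraries compared, 427 were shared higher and 354 lower. The test of the difference itself called 0 genes with limma, and 317 genes had an unadjusted p under 0.05, or 1.58% of those tested. It called 1 gene without WS BO flight replicate 2. In simulated data for this test, 12 of 50 genes whose effects differed by 1 on the log2 scale were recovered, and 42 of 50 that differed by 2. Of the 27 lists, 0 passed camera for the difference (adjusted p between 0.301 and 0.964), and 0 members were called by limma, over all genes or adjusted over the list alone. Leaving out 1 library gave 3 passing lists without sku5 BO ground replicate 1 or 2, 2 without WS BO ground replicate 1 or 2, and 1 without WS BO flight replicate 2, sku5 BO flight replicate 1 or sku5 BO ground replicate 3. Without WS BO ground replicate 1, sugar starvation genes passed in the opposite direction (0.0133). For the difference, the median, the mean and the camera direction did not share a sign for peroxidase, touch, light, jasmonate and reference genes. For SKS1, the difference was -0.08 (SE 0.27), and for SKU5 it was 0.00 (SE 0.34).

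**Figure D3:**
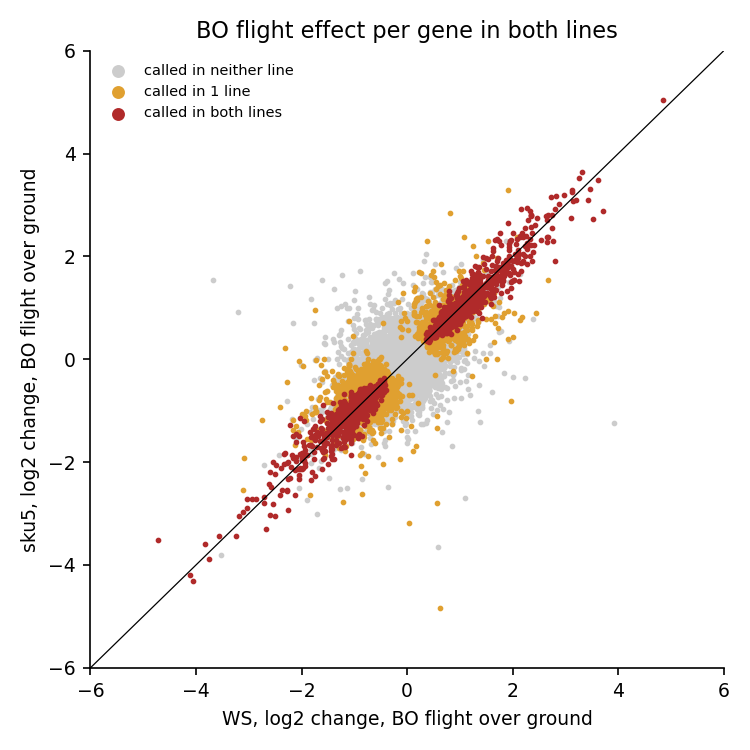
Log2 change per gene, BO flight over ground, in WS (horizontal) and sku5 (vertical), 1 point per tested gene, coloured by whether limma called it in both lines, in 1 line or in neither; MT1A is left out. The 787 genes higher and 671 lower in both lines lie along the line of equal change.

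The VG flight of WS asks how the same wild type responds to a flight that a carrier aircraft lifts before rocket ignition. Few transcripts were called between flight and ground. A repressor of ethylene signalling was lower in flight. Lists of cell wall, root hair and folding genes leaned higher and a defence list leaned lower, each with an adjusted p of 0.477 with an estimated correlation. Photosynthesis genes, markers of shoot tissue, leaned higher with them (median log2 change 0.33, camera adjusted p = 0.00103, and 0.477 with an estimated correlation).

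In WS at VG, limma called 6 of 20127 genes, 2 higher and 4 lower in flight, and 1884 had an unadjusted p under 0.05. The count was 21 without flight replicate 1, 14 without ground replicate 2, 3 without flight replicate 2 and 3 without ground replicate 3. It was 18 with no filter, 10 with a pseudocount of 0.1, 3 with photosynthesis genes as a covariate, 2 with the replicate block, 1 with only the libraries compared and 0 with genes above 0 in every library. EBF2 (AT5G25350), an F-box protein that targets the ethylene transcription factor EIN3 for degradation, fell by 1.12 (SE 0.18, limma adjusted p = 0.0422) from 87.1 ± 4.31 to 39.8 ± 5.52 FPKM (SD, n = 3). Its call was lost without flight replicate 2 (-1.03) or 3 (-1.11) and without ground replicate 1 (-1.13), 2 (-1.14) or 3 (-1.08). The other 5 called genes fall outside the rule for named genes and were chosen after their values were seen. LURP1 (AT2G14560), a defence gene, lay at 1.1, 0.63 and 0.64 FPKM in flight and at 7.49, 2.79 and 11.63 on the ground (log2 change -2.06). AT2G41050 lay at 8.35, 6.28 and 7.14 FPKM in flight and at 3.15, 1.92 and 1.64 on the ground (log2 change 1.37). The other 3 were listed at 0 in all 3 libraries of 1 group. AT3G06895 had 7.55, 27.05 and 28.39 FPKM in flight, AT2G05230 had 12.23, 18.35 and 8.14 on the ground, and AT2G43530 had 5.56, 2.75 and 6.68 on the ground. AT3G06895 shares 55.3% and AT2G05230 96.4% of its 50-base words with another gene, so their values are uncertain. AT2G05250 lay at 23.02, 31.25 and 24.94 FPKM in flight and at 12.31, 1.4 and 15.55 on the ground, opposite to AT2G05230. Whether reads moved between these 2 genes was not tested. SKU5 was not called (log2 change 0.44, SE 0.24), nor was SKS1 (0.24, SE 0.19). In simulated data for this comparison, 30 of 50 genes changed by 1 on the log2 scale were recovered, and 46 of 50 changed by 2.

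For WS at VG, 9 lists passed camera with the preset correlation, 6 higher and 3 lower, and 0 passed with an estimated correlation, while 0 of their members were called by limma over all genes. Cell wall genes leaned higher (median 0.57, camera adjusted p = 1.96e-05, and 0.477 with an estimated correlation), with 4 higher adjusted over the list alone. Among these, XTH19 had a log2 change of 1.90 (SE 0.34). Root hair genes leaned higher (median 0.65, adjusted p = 7.18e-05, and 0.477 with an estimated correlation), with 2 higher adjusted over the list alone. Endoplasmic reticulum folding genes did so as well (median 0.43, adjusted p = 1.96e-05, and 0.477 with an estimated correlation), with 0 adjusted over the list alone. Photosynthesis genes (median 0.33, adjusted p = 0.00103, and 0.477 with an estimated correlation) had 2 higher adjusted over the list alone, and dividing-cell genes (median 0.36, adjusted p = 0.00936, and 0.477 with an estimated correlation) had 1. Cold, drought and abscisic acid genes had a median of 0.42 (adjusted p = 0.0215, and 0.634 with an estimated correlation), but without flight replicate 2 the direction of this test reversed (0.67) and without ground replicate 2 its adjusted p was 0.51. Adjusted over the list alone, the cold, starvation and early stress lists had 0 called. Defence genes leaned lower (median -0.65, adjusted p = 0.00194, and 0.477 with an estimated correlation), with 1 lower adjusted over the list alone. Sugar starvation genes leaned lower (median -0.45, adjusted p = 0.00215, and 0.634 with an estimated correlation), but not past the threshold without flight replicate 2 (0.0775) or ground replicate 3 (0.0642). Early stress transcription factors leaned lower (median -0.33, adjusted p = 0.0215, and 0.534 with an estimated correlation), but not without flight replicate 2 (0.28), ground replicate 2 (0.166) or ground replicate 3 (0.0636). Dividing-cell genes did not pass without flight replicate 1 (0.0528) or ground replicate 3 (0.0582). Without the 3 libraries that stood apart, the defence (0.072), sugar starvation (0.072) and early stress (0.193) calls were lost and the cold list reversed (0.662). The defence call was also lost with no filter (0.187), and the early stress and cold calls with photosynthesis genes as a covariate (0.217 each). The other 18 lists had camera adjusted p between 0.086 and 0.954 and 0 members called by limma over all genes. Of these, the hypoxia list alone had a member adjusted over the list alone, the ethylene receptor gene ETR2 (log2 change -1.11, SE 0.25). For touch and clock genes, the median and the camera direction or mean did not share a sign.

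**Figure D4:**
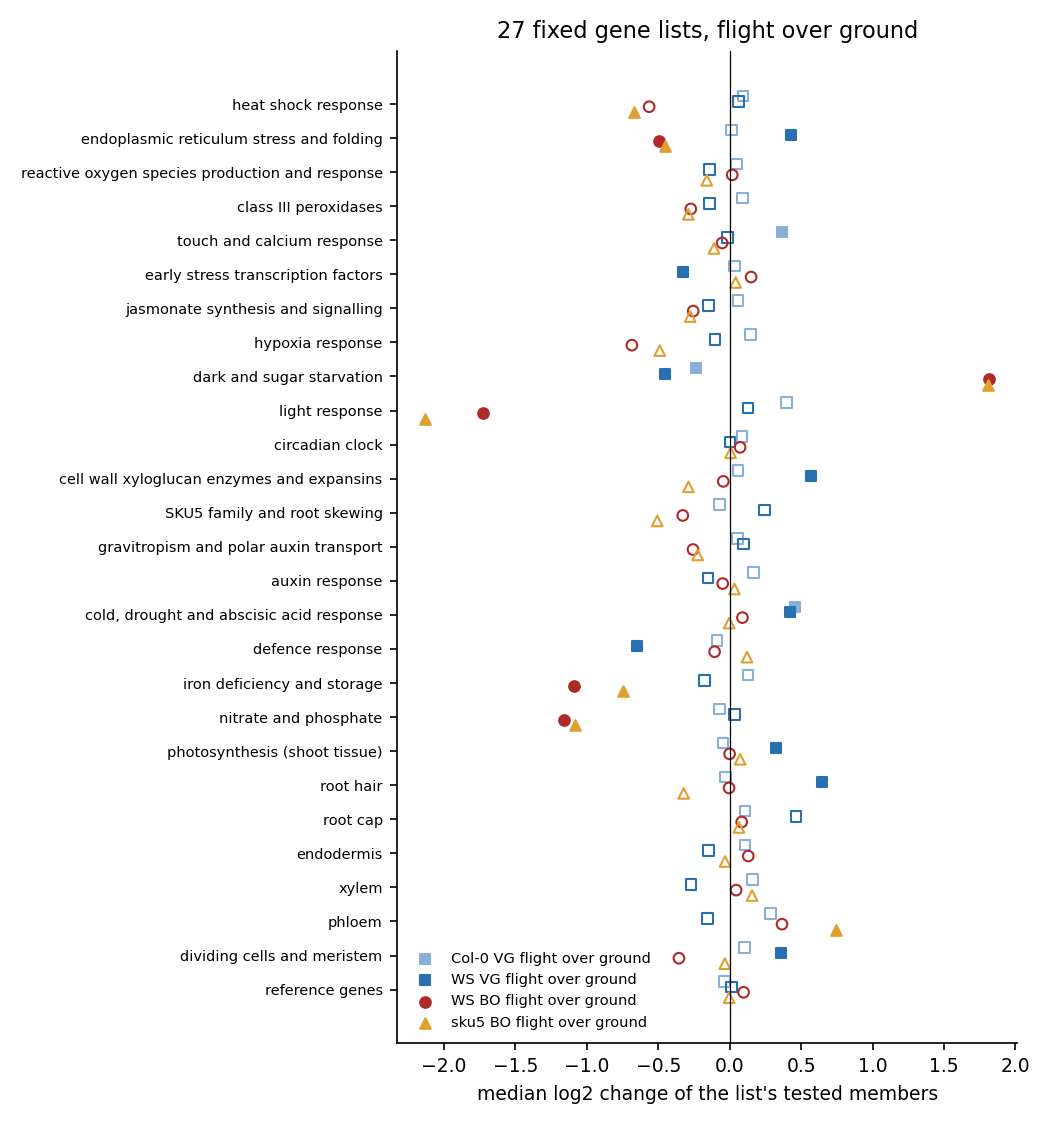
Median log2 change of the tested members of each of 27 fixed gene lists in the 4 flight comparisons. Filled symbols passed camera with a preset correlation of 0.01 at an adjusted p under 0.05, open symbols did not, and none passed with an estimated correlation; sugar starvation and light genes lie farthest from 0, in the BO comparisons.

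The VG flight of Col-0 asks the same of the common laboratory wild type. Hardly any transcript was called between flight and ground in this line, where the fit had 4 residual degrees of freedom. The 1 gene called was listed at 0 in flight. The touch and cold lists leaned higher and the sugar list lower by small amounts, each with an adjusted p of 0.775 with an estimated correlation.

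In Col-0 at VG, limma called 1 of 18786 genes, lower in flight, and 926 had an unadjusted p under 0.05, or 4.93% of those tested. AT1G61280 was listed at 0 in all 3 flight libraries and at 8.50, 10.86 and 15.48 FPKM on the ground (limma adjusted p = 0.0425), so no fold is given. Its call was lost without flight replicate 1, 2 or 3, and without any 1 ground replicate it did not pass the filter. The count was 0 without flight replicate 1, flight replicate 2 or ground replicate 1, 2 without flight replicate 3, 3 without ground replicate 2 and 1 without ground replicate 3, and no gene of these was shared with the fit of all 6 libraries. It was also 0 with no filter, the filter at 5 FPKM, pseudocounts of 0.1 and 5, the replicate block, genes above 0 in every library and photosynthesis genes as a covariate, and 4 without trend. EBF2 lay at 38.75, 33.05 and 44.99 FPKM in flight and at 85.84, 88.28 and 84.60 on the ground (log2 change -1.14, SE 0.15, limma adjusted p = 0.117), chosen after its values were seen. SKU5 was not called (log2 change 0.10, SE 0.16), nor was SKS1 (-0.09, SE 0.35). In simulated data for this comparison, 21 of 50 genes changed by 1 on the log2 scale were recovered, and 46 of 50 changed by 2. With camera, 3 lists passed with the preset correlation and 0 with an estimated correlation. Cold, drought and abscisic acid genes leaned higher (median 0.46, adjusted p = 2.9e-07, and 0.775 with an estimated correlation), with 1 higher adjusted over the list alone, the phosphatase gene HAI1. Touch and calcium genes leaned higher (median 0.37, adjusted p = 0.00828, and 0.775 with an estimated correlation), with 1 higher adjusted over the list alone, the calmodulin-like gene TCH2. The touch call was lost without flight replicate 1 (0.402) and ground replicate 1 (0.0948). Sugar starvation genes leaned lower (median -0.24, adjusted p = 0.000996, and 0.775 with an estimated correlation), with 0 adjusted over the list alone, and did not pass without flight replicate 2 (0.386) or ground replicate 3 (0.0555). The other 24 lists had camera adjusted p between 0.13 and 0.99. Without 1 library, xylem (0.0121 without flight replicate 3), photosynthesis (0.00121 without ground replicate 2) and iron genes (0.00601 without ground replicate 3) passed. Limma called 0 members of any list over all genes, and the early stress list had 1 lower adjusted over the list alone. The median, the mean and the camera direction did not share a sign for cell wall, nitrate and phosphate, photosynthesis and root cap genes. Whether Col-0 and WS differ in their VG responses was not tested.

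The WS line flew on both vehicles. Whether the VG ground plates were in light during the flight is not stated in the labels, so light could not be compared between the vehicles, and the other conditions change together with them. They differed for 1375 of 20127 genes. These include 15 of 17 sugar starvation genes, with a higher change at BO, and 9 of 22 folding genes, with a lower one (adjusted p = 0.319 and 0.463 with an estimated correlation).

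The test of the difference between the WS flight effects at BO and at VG called 1375 of 20127 genes with limma, 731 with a higher change at BO and 644 with a lower one. The count was 467 without BO ground replicate 1, 530 without VG ground replicate 3, 616 without VG flight replicate 2, 649 without VG ground replicate 1, 715 without BO flight replicate 3, 780 without BO ground replicate 3 and 881 without BO flight replicate 1. It was 848 with photosynthesis genes as a covariate, which leaned higher in WS at VG (median 0.33). Across genes, Pearson's r of the WS log2 changes at VG and BO was -0.11, and 0 genes were called in the same direction in both. Independent lists of those sizes would share only 0.11 higher and 0.25 lower, so the 0 decides nothing. Without VG flight replicate 3, 1 gene was shared higher, and without VG flight replicate 1, 2 were shared lower. EBF2 was called in both, lower in flight at VG and higher in flight at BO (log2 change 0.61, SE 0.18, limma adjusted p = 0.0376). Between Col-0 and WS at VG, r was 0.13 across 18361 genes, with 0 shared calls. EBF2, chosen after its values were seen, is in both VG lists that the authors deposited. Its log2 fold change there was -1.14 in Col-0 and -1.13 in WS. Among the named genes, the largest differences were 5.40 for SEN1 (SE 0.80) and 4.27 for BCAT-2 (SE 0.87) in the direction of a higher change at BO. ELIP1 (-5.41, SE 0.72) and TT5 (-4.99, SE 0.71) differed most in the other direction. TT4 differed by -4.02 (SE 0.93), a call lost without BO ground replicate 1 (-3.98) or VG ground replicate 3 (-3.88). It lay at 542 ± 94.4 FPKM in WS BO ground libraries, 39.4 ± 36.8 in BO flight, 1.31 ± 1.05 in VG ground and 1.17 ± 0.825 in VG flight. SKU5 was not called (-0.95, SE 0.34). SKS1 was not called either (-0.88, SE 0.27), but was called without BO flight replicate 2, VG flight replicate 3 or VG ground replicate 2 (-1.0 in each).

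Of the 27 lists, 7 passed camera for this difference with the preset correlation and 0 with an estimated correlation, 2 higher at BO and 5 lower. Of 17 sugar starvation genes, limma called 15 with a higher change at BO (16 adjusted over the list alone; median 2.42, camera adjusted p = 2.36e-18, and 0.319 with an estimated correlation). Folding genes had 9 lower of 22 (14 adjusted over the list alone; median -0.93, camera adjusted p = 1.53e-06, and 0.463 with an estimated correlation). Light genes had 1 higher and 6 lower of 12 (2 and 8 adjusted over the list alone; median -1.99, camera adjusted p = 0.00402, and 0.463 with an estimated correlation). Cell wall genes had 1 higher and 5 lower of 25 (1 and 8 adjusted over the list alone; median -0.81, camera adjusted p = 0.00251, and 0.556 with an estimated correlation). Nitrate and phosphate genes had 2 lower of 9 (3 adjusted over the list alone; median -1.49, camera adjusted p = 0.0017, and 0.319 with an estimated correlation). Early stress transcription factors had 1 higher of 16 (4 adjusted over the list alone; median 0.47, camera adjusted p = 0.0462, and 0.556 with an estimated correlation). This call was lost without BO flight replicate 2 (0.169), BO ground replicate 1 (0.0692) or 3 (0.0878), VG flight replicate 1 (0.0538) or 2 (0.0959), or VG ground replicate 2 (0.0967), with a TMM factor (0.0556), with the filter at 5 FPKM (0.0757), without the 3 libraries that stood apart (0.0651) and with photosynthesis genes as a covariate (0.104). Dividing-cell genes had 0 called of 8 by limma (2 lower adjusted over the list alone; median -0.87, camera adjusted p = 0.0376, and 0.556 with an estimated correlation), a call lost without BO flight replicate 2 (0.0615), BO ground replicate 1 (0.0712) or VG flight replicate 1 (0.0727) and with the filter at 5 FPKM (0.0757). The other 20 lists had camera adjusted p between 0.07 and 0.828. Under the alternatives, 13 results of lists that had not passed did pass. In the main fit, the 20 lists that did not pass still had called members. Limma called 2 higher and 4 lower heat shock genes, 4 and 1 hypoxia genes, and 2 and 1 clock genes. It called 1 and 2 touch genes, 1 and 1 photosynthesis genes, 0 and 2 jasmonate genes, and at most 1 gene of any other of these lists. For peroxidase and auxin response genes, the median, the mean and the camera direction did not share a sign. In simulated data for this test, 11 of 50 genes whose effects differed by 1 on the log2 scale were recovered, and 46 of 50 that differed by 2.

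The authors deposited their own lists of changed genes for the 4 flight comparisons, in which every p-value lay under 0.01 and every absolute log2 fold change above 1. These lists hold 13 genes for Col-0 at VG, 57 for WS at VG, 865 for WS at BO and 923 for sku5 at BO. Every gene of these lists that passed the filter here (9, 56, 864 and 917) changed in the same direction in the FPKM values. Limma called 844 of the 864 WS BO genes (97.7%) and 854 of the 917 sku5 BO genes (93.1%), but 4 of the 56 WS VG genes and 1 of the 9 Col-0 VG genes. Of the deposited genes, 4 in Col-0 at VG, 23 in WS at VG, 8 in WS at BO and 29 in sku5 at BO were listed at 0 FPKM in all 3 libraries of 1 group.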

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

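The tests of light, harvest hour, shoot tissue, a chromosome segment, and reads shared with another gene for genes listed at 0 were chosen after the results were seen; the other tests in this part were set down before.

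An interaction contrast set a difference between groups apart: the WS flight effect at BO differed from that at VG for 1375 genes. The count was 467 without BO ground replicate 1, 530 without VG ground replicate 3, 616 without VG flight replicate 2, 649 without VG ground replicate 1, 715 without BO flight replicate 3, 780 without BO ground replicate 3 and 881 without BO flight replicate 1. It was 848 with photosynthesis genes as a covariate, which leaned higher in WS at VG (median 0.33). Among the named genes, the largest differences in log2 change toward a higher change at BO were 5.40 for SEN1, 4.27 for BCAT-2, 4.1 for ATL8, 3.87 for SWEET12 and 3.86 for ASPGB1. The largest in the other direction were -5.41 for ELIP1, -4.99 for TT5, -4.29 for FLS1, -4.02 for TT4 and -3.62 for TT7. Among list members with the smallest p were TPS9 (2.02), WRKY40 (1.71), P58IPK (-1.18), EXPA1 (-1.32) and NIA1 (-2.71). Of these, TT4 lost its call without BO ground replicate 1 (-3.98) or VG ground replicate 3 (-3.88). P58IPK lost its call without the same libraries (-1.08 and -1.07), and EXPA1 without BO ground replicate 1 (-1.25), VG ground replicate 1 (-1.15) or VG ground replicate 3 (-1.14). By list, the median difference was 2.42 for dark and sugar starvation, 0.47 for early stress transcription factors, -0.93 for endoplasmic reticulum folding, -1.99 for light, -0.81 for cell wall, -1.49 for nitrate and phosphate and -0.87 for dividing-cell genes. These lists passed camera with the preset correlation, and 0 lists passed with an estimated correlation. The early stress list lost its call without BO flight replicate 2 (camera adjusted p = 0.169), BO ground replicate 1 (0.0692) or 3 (0.0878), VG flight replicate 1 (0.0538) or 2 (0.0959) or VG ground replicate 2 (0.0967). The dividing-cell list lost its call without BO flight replicate 2 (0.0615), BO ground replicate 1 (0.0712) or VG flight replicate 1 (0.0727). Of 100 splits of the 12 libraries, the real one alone gave as many genes, and the highest other gave 680. These splits exchange flight and ground libraries within each vehicle, so they also break the flight effect at BO. They therefore cannot decide whether the effects differ between the vehicles. Vehicle, year, site, age and growth conditions differ together between BO and VG, so their parts in this difference cannot be told apart.

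After the BO flight, sugar starvation genes were higher, and the flavonoid genes TT4, FLS1, TT5 and TT7 lower, than in ground controls. No list of flavonoid genes was tested. Unequal shoot tissue as the only cause is argued against. The photosynthesis list had a median log2 change of 0.073 in sku5, where the starvation list had 1.81 (SD of the photosynthesis members 0.62). It passed camera in sku5 without flight replicate 2 (adjusted p = 0.0471) or ground replicate 2 (0.0169). Light may shift photosynthesis genes too, so a part for shoot tissue beside darkness stays open. Darkness stays open, since the flight plates were wrapped in black-out cloth. The 44 called members of the starvation list and the light-induced part of the light list, 22 in each line, moved as darkness would move them, but these genes are the pattern itself and decide nothing. Harvest 1 h later on the ground cannot be told apart from it, because morning clock genes lay above evening clock genes by a median of 2.43 in WS and 1.97 in sku5, which light can also shift, and both go with the flight groups. A response to the flight itself stays open and was not tested, because wrapping and harvest time differ in the same way between flight and ground.

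Between sku5 and WS on the ground, genes with low p-values lay close together on 1 arm of chromosome 5, while SKU5 lies on chromosome 4. Of the 50 genes with the lowest p, 14 lay within 100 neighbouring tested genes, against at most 6 in 10000 random orders (permutation p = 1e-04, the smallest these orders can give). Shared reads are argued against, since 1 of the 14 genes had over 50% of its 50-base words in another gene. A chromosome segment that differs between the lines may explain the group, Fes1C included: 12 of the 14 differed in the same direction in the flight libraries, and 12 had an unadjusted p under 0.05 there, against 27 and 10 of the other 36. BSK10, among these 36, lies on the same arm with 22 tested genes between it and the window, and was lower in sku5 in the flight libraries too (log2 change -2.17, SE 0.24, limma adjusted p = 0.000922). An effect of the SKU5 mutation on these genes stays open and was not tested.

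In the WS and sku5 table, 320 genes were listed at 0 in some library of a group and at 5 FPKM or more in another of the same group, as were 286 genes of the Col-0 table. Too few reads are argued against only as far as the rough scale of 33.2 counts per FPKM and kilobase holds for each library. At this scale, the expected count from the mean of the other libraries of the group had a median of 136 and a lower quartile of 83.6. It was under 20 for 1 of 315 genes and under 5 for 0. The choice of genes at 5 FPKM or more alone puts that median at 52 or above at this scale. Since the test asked for a median over 20, its outcome was fixed by the choice and adds nothing to the scale. Depth per library is unknown. Reads shared with another gene are a likely source for part of them: 24.1% (76 of 315 searched) had over 50% of their words in another gene, against 3.55% of the other tested genes (701 of 19741; Fisher's exact test, two-sided p = 5.59e-39). No explanation was tested for the rest. AT1G61280, listed at 0 in all Col-0 flight libraries, had 0% shared words. Of the genes called at VG, 1 of 1 in Col-0 and 3 of 6 in WS had a value of 0 in at least 1 of the 6 libraries compared.

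Other splits of the libraries were fitted for each comparison. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In Col-0 at VG, 6 splits, the real one (1 gene) included, called as many genes, and the highest other called 6. In WS at VG, 1 split did, the real one with 6 genes, and the highest other called 3. In WS at BO, 1 did, the real one with 2345 genes, and the highest other called 0. In sku5 at BO, 1 did, the real one with 2072 genes, and the highest other called 126. Between sku5 and WS on the ground, 2 did, the real one with 3 genes, and the highest other called 4. For the difference of the BO flight effects between lines, the real split called 0 genes, so all 100 splits call at least as many and the count decides nothing about chance. The highest other called 5246 genes. The splits allow all flight and ground libraries of 1 line to be exchanged, which turns the difference of the 2 effects into their sum. Which split gave 5246 was not identified, so no structure of the samples is read from it.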

How the results depend on the processing

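Alternatives chosen after seeing the data were genes above 0 in every library, the fits without 3 libraries that stood apart, an adjusted p under 0.01 with a log2 change of at least 1, and photosynthesis genes as a covariate. For moved results the cause was not tested, except that stricter thresholds pass fewer genes by construction and fits with fewer libraries have fewer degrees of freedom.

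Of the values of named genes under the alternatives, 1256 in WS at BO kept their direction and side of the threshold, 122 lost the call and 1 gained it. In sku5 at BO 1160 kept both, 147 lost the call and 1 gained it, and for the difference of the WS flight effects 1056 kept both, 159 lost it and 7 gained it. No named gene reversed. EBF2 in WS at VG lost its call without trend, with the replicate block, with only the libraries compared, with genes above 0 and with the covariate, at log2 changes of -1.12 and -1.20. In Col-0 at VG the count of 1 became 0 under no filter, the stricter filter, pseudocounts of 0.1 and 5, the replicate block, genes above 0, the covariate and the stricter threshold, and 4 without trend. In WS at VG the count of 6 became 18 with no filter, 10 with a pseudocount of 0.1, 3 with the stricter threshold, 3 with the covariate, 2 with the replicate block, 1 with only the libraries compared and 0 with genes above 0. A minimum log2 change of 1 gave 972 genes in WS at BO and 929 in sku5, and the stricter threshold gave 588 and 545. With only the libraries compared, sku5 at BO had 942, WS at BO 3257 and sku5 against WS on the ground 1. The difference of the WS flight effects had 253 genes with the stricter threshold and 848 with the covariate. TMM and quantile scaling left the total of called genes within 1.5 times in each comparison, but with quantile normalization WS at VG had 5 higher and 4 lower in place of 2 and 4.

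Genes shared higher between WS and sku5 at BO numbered 326 at an adjusted p under 0.01, 357 with a log2 change of at least 1 and 427 with only the libraries compared, and genes shared lower 209, 281 and 354. WS at VG and BO shared 1 lower gene with no filter. With an estimated correlation 0 lists passed in each comparison. Without the 3 libraries, 5 lists passed in WS at VG, 7 in sku5 against WS on the ground and 2 for the difference between lines, where only the libraries compared gave 1. Genes above 0 gave 3 lists in WS at BO and 3 in sku5, and sku5 had 4 with the stricter filter and 4 with the replicate block.

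Some list directions reversed. The cold and abscisic acid list in WS at VG did so without the 3 libraries (0.662) and without flight replicate 2 (0.67), with 5.4e-05 to 0.67 over single libraries left out. The iron list in sku5 against WS did so without the 3 libraries (0.0057) and without sku5 BO ground replicate 3 (0.00331), with 0.00248 to 0.829 over single libraries. The starvation list reversed in sku5 against WS without WS BO ground replicate 2 (0.899; range 9.35e-09 to 0.899), and for the difference between lines without WS BO ground replicate 1 (0.0133; range 0.0133 to 0.954).

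Leaving out 1 library at a time gave 0 to 3 genes in Col-0 at VG, 3 to 21 in WS at VG, 879 to 1962 in WS at BO, 1082 to 2194 in sku5 at BO, 2 to 3 in sku5 against WS, 0 to 1 for the difference between lines and 467 to 1878 for the difference of the WS flight effects. Passing lists ran from 2 to 4, 6 to 9, 4 to 7, 3 to 7, 6 to 9, 0 to 3 and 5 to 9 in the same order. Shared genes at BO ran from 430 to 824 higher and 316 to 631 lower, those between WS at VG and BO from 0 to 1 higher and 0 to 2 lower, and those between Col-0 and WS at VG stayed at 0. Read totals were not given, so limits from depth could not be set. Alternatives written for tables of counts were not run.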

Other observations

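The test of ethylene genes was set down before its result was seen; the other values in this part were chosen after the data were seen.

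EBF2, which ethylene induces, was lower after the VG flight, and a lower ethylene response is a candidate explanation. The 6 other ethylene-induced genes tested in WS had a median log2 change of -0.30, and 4 of the 6 were lower. In Col-0 the median was -0.40 with 5 of 5 lower, none of them called by limma. Of these 5, EBF1 lay at -0.0039 (SE 0.13). Only ERS1 had an unadjusted p under 0.05 (log2 change -0.67, SE 0.15, limma unadjusted p = 0.0014). ETR2, an ethylene receptor gene outside the 6 set for the test, had -1.11 in WS (SE 0.25, limma adjusted p = 0.171) and -0.50 in Col-0 (SE 0.28), which goes with a lower response. WS at BO, where EBF2 was higher in flight, had a median of 0.11. Since fewer than 5 of the 6 were lower in WS, the prediction was not met, and the hypothesis cannot be told apart from a change of EBF2 alone with 3 libraries per group.

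The iron uptake genes varied between ground replicates at BO. IRT1 lay at 510.44, 96.44 and 264.08 FPKM in WS ground libraries and at 788.25, 353.59 and 78.40 in sku5 ground libraries, against 16.18 to 64.09 and 31.98 to 66.70 in flight.

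Among genes called in WS at BO, the mean of the WS VG libraries lay nearer the BO flight mean than the BO ground mean for 1612 of 2345 (68.7%). Among those called in sku5 at BO it did so for 1570 of 2072 (75.8%). VG and BO libraries differ in vehicle, year, site, age and growth conditions.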
